A study of Homo sapiens with 6 samples.

How the data were processed

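RNA was measured by sequencing in 6 libraries of TOV21G cells, 3 with a scrambled control hairpin and 3 with a hairpin against MEX3A. Per the labels' protocols, the cells grew in medium with 15% serum for at most 25 passages, were transduced at a multiplicity of infection of 50, and gave total RNA on day 3, from which mRNA libraries were prepared with a KAPA kit. The authors deposited one table of raw read counts per gene, with one column per library and whole numbers throughout. Per the submitters' processing notes, fastp 0.20.0, STAR, HTSeq 2.0.4 and edgeR 4.0.16 were used with GRCh38, and no role or order is given there. The STAR version, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart. Of the named genes this touches TOMM6 most, with 100% of its exon bases under exons of another gene, followed by DUSP6 (40.5%), NDUFV2 (28.4%), TGFB2 (26.6%), VIM (24.4%) and MRPS25 (22.2%).

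The table held 42656 rows, of which 41709 carried a symbol of the RefSeq gene table, and the other rows held at most 0.426% of a library's counts. Library totals ran from 34662635 to 48228216 counts. Libraries of one arm differed by more than sampling noise, with a chi-square per degree of freedom of 2.69 to 6.15 over genes with at least 20 counts in a pair, so none was treated as a duplicate. Between arms the same value was 138 to 184.

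Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15679, and libraries were scaled by TMM. The quasi-likelihood fit was robust, had 4 residual degrees of freedom and gave a common biological coefficient of variation of 3.41%. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Levels are counts scaled by TMM to a common library total (CPM) with the SD over 3 libraries, and the standard error of a log2 fold change was taken from its F statistic. The 40 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. They were tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes.

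The genes named in the text follow a rule fixed before the data were examined. It takes the MEX3 family, the 10 largest rises and 10 largest falls among called protein-coding genes with fully parted groups and an average of at least 3 log2 CPM, and in each described list the 2 called members with the smallest p in each direction. Readthrough genes were removed by the form of their symbol, which also removed HLA-DMA and HLA-DMB, neither of which would have ranked among the 10. Some results under this rule, and the account of a gene list, are not reported here. ND6, TWIST1 and ZEB1 are named outside the rule and were chosen after their values were seen.

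The alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of at least 1 CPM, DESeq2 1.42.0, limma voom, the replicate number as a block, mitochondrially encoded genes left out, and each library left out in turn. Added after seeing the data were offsets for GC content and transcript length (natural splines with 5 degrees of freedom, on the 14173 tested genes with a value in GENCODE 29) and a fit without carriers of a 3' UTR motif. 3' UTRs came from GENCODE 29. The 7-mer scan covered 12853 coding genes with a 3' UTR of at least 50 bases and 15940 7-mers, each present in at least 100 genes. It adjusted fold changes for GC content and length and drew 1000 permutations of the genes. It ran in Python with numpy and scipy.

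The tests were checked on simulated data. Over 15471 simulated genes for the comparison of the arms, with 200 genes changed, the edgeR test recovered 45 of 67 genes changed 1.25-fold, 51 of 67 changed 1.5-fold and 54 of 66 changed 2-fold, with 11 false calls among 161. A limit of 90% on recovery of the 2-fold genes had been set and was not met, so recovery was broken down by level. Over 10 CPM the test recovered 41 of 41 genes changed 2-fold, from 1 to 10 CPM 11 of 12, and under 1 CPM 2 of 13, so changes of weakly expressed genes can be missed. Only 200 genes were changed here, in both directions, whereas 69.7% of tested genes were called in the real data. Recovery, false calls and TMM scaling were therefore not checked for data in which most genes change. In a second simulation with a GC trend added, the test called 8614 genes without correction and 160 with it, where 186 had been changed. Camera recovered 3 of 3 shifted lists and called 0 others. The simulated genes were drawn independently of each other, so this does not check false calls in lists of correlated genes. For complex I subunits the correlation estimated in the real data was 0.433. For the 7-mer scan, a first test that planted 5 shifts and asked for all of them recovered 4. The test was then widened to 200 planted shifts of -0.25 in log2, of which 193 ranked first. With at least 500 carriers 138 of 138 did, and with fewer carriers 55 of 62.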

Results

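The series measured messenger RNA in TOV21G, an established cell line from an ovarian clear cell carcinoma, after lentiviral delivery of short hairpin RNAs. One arm received a scrambled control hairpin (shCtrl) and the other a hairpin against MEX3A (shMEX3A), an RNA-binding protein with KH domains and a RING domain. Each arm has 3 libraries, made from RNA collected on day 3. The counts per library summed to between 34662635 and 48228216. The one comparison of the design asks how gene expression differs when MEX3A is depleted, and the title of the series ties that question to mitochondrial fitness. Each arm used 1 hairpin.

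MEX3A itself was lower in all 3 shMEX3A libraries. Its level was 69.0 ± 1.54 CPM in shCtrl and 20.9 ± 1.31 CPM in shMEX3A (SD, n = 3 each), a 3.31-fold lower level (log2 fold change -1.72, SE 0.046, adjusted p = 1.52e-28, edgeR quasi-likelihood test). The gene lies on chromosome 1 from 156072013 to 156081998 on the minus strand (GRCh38, GENCODE 29), and none of its exon bases lie under another gene's exons. The 3 other members of the family were higher in shMEX3A. MEX3D rose from 62.2 ± 1.53 to 114 ± 3.01 CPM (log2 fold change 0.88, SE 0.036), MEX3C by 0.37 (SE 0.037) and MEX3B by 0.21 (SE 0.063) on the log2 scale. The rise of MEX3B lost its call when shCtrl replicate 3 was left out (adjusted p = 0.0506) and with offsets for GC content and length (log2 fold change 0.05, adjusted p = 0.475), an alternative chosen after seeing the data.

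**Figure D1:**
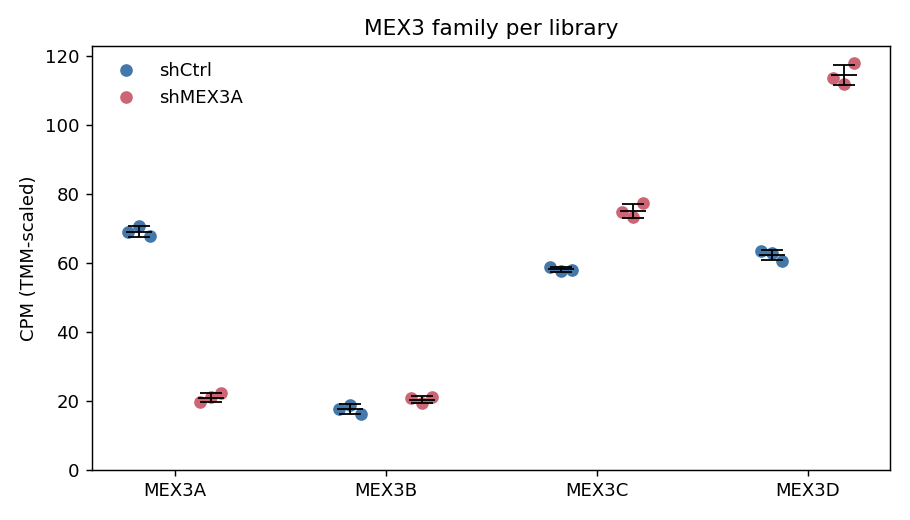
Level in TMM-scaled CPM (vertical axis, from 0) of the 4 MEX3 genes (horizontal axis) in each of 3 shCtrl and 3 shMEX3A libraries (points), with the mean and SD as bars. MEX3A falls from 69.0 to 20.9 CPM, while MEX3D rises from 62.2 to 114 CPM.

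Most tested genes differed between the arms. Of 15679 genes tested, 10925 (69.7%) passed an adjusted p of 0.05, with 5336 higher and 5589 lower in shMEX3A. At least 2-fold changes were found for 1090 genes that rose and 871 that fell. The groups were fully apart in 11331 of the tested genes (72.3%), where chance alone would part 10% of genes in a comparison of 3 with 3. The median log2 fold change over all tested genes was -0.01. TMM scaling takes most genes as unchanged, so a median near 0 and similar numbers of rises and falls could be foreseen. Rises and falls are thus relative to the other genes, and a change in total mRNA would not be seen. The first principal component held 77.6% of the variance and parted the arms, and the second held 8.52%, with shCtrl replicate 1 farthest from the other libraries on it. The labels do not say whether the 3 libraries of an arm came from separate cultures, so p-values measure the spread between these samples, which may be technical.

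COL1A1, TFPI2 and PMEPA1 were among the genes with the largest rises. COL1A1, a chain of type I collagen, rose from 13.1 ± 0.730 to 117 ± 5.60 CPM (log2 fold change 3.16, SE 0.047). TFPI2, a Kunitz-type protease inhibitor used as a marker of clear cell carcinoma, rose from 69.0 ± 3.08 to 605 ± 10.7 CPM (3.13, SE 0.035). PMEPA1, a TGF-beta-induced membrane protein, reached 257 ± 2.15 CPM from 41.4 ± 1.49 CPM (2.63, SE 0.035). The insulin-like growth factor binding protein IGFBP3 rose by 2.60 and the interferon-induced GTPase MX1 by 2.52 on the log2 scale. Large rises were also found for the MAP kinase phosphatase DUSP8 (2.34), the phosphodiesterase PDE2A (2.23), the metalloprotease ADAM19 (2.19) and the activin subunit INHBA (2.16).

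The largest falls were in MAT2A and RPS24. MAT2A, the enzyme that makes S-adenosylmethionine in most tissues, went from 2681 ± 81.8 to 434 ± 4.91 CPM (log2 fold change -2.63, SE 0.032). RPS24, a protein of the small ribosomal subunit, went from 654 ± 40.0 to 108 ± 2.13 CPM (-2.59, SE 0.038), and reads shared with pseudogene copies were not examined here. The prolyl hydroxylase EGLN3 fell from 48.0 ± 1.59 to 7.94 ± 0.612 CPM (-2.59, SE 0.060). PELI2, a ubiquitin ligase, changed by -2.49 and CPE, which trims prohormones, by -2.38 on the log2 scale. NOSTRIN (-2.33), the bicarbonate transporter SLC4A4 (-2.29), the secreted protease HTRA1 (-2.23), the procollagen protease ADAMTS3 (-2.21) and PDCL3 (-2.10) complete the 10 largest falls.

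Messenger RNAs encoded in the mitochondrial genome rose together. Of 13 tested, 12 rose and 0 fell, with a median log2 fold change of 1.08, and the other, ND6, had 0.87 with an adjusted p of 0.0699. COX1 rose from 4079 ± 107 to 8444 ± 405 CPM (log2 fold change 1.05, SE 0.034) and COX2 from 897 ± 50.8 to 2124 ± 43.8 CPM (1.24, SE 0.034), both being subunits of cytochrome c oxidase. These mRNAs made up 1.60% ± 0.058 of counts in shCtrl and 3.21% ± 0.129 in shMEX3A (SD, n = 3). The mitochondrial rRNAs made up 0.612% ± 0.016 and 0.784% ± 0.028 of counts. The list passed camera with an adjusted p of 2.68e-05 (adjusted p = 0.213 with an estimated correlation).

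**Figure D2:**
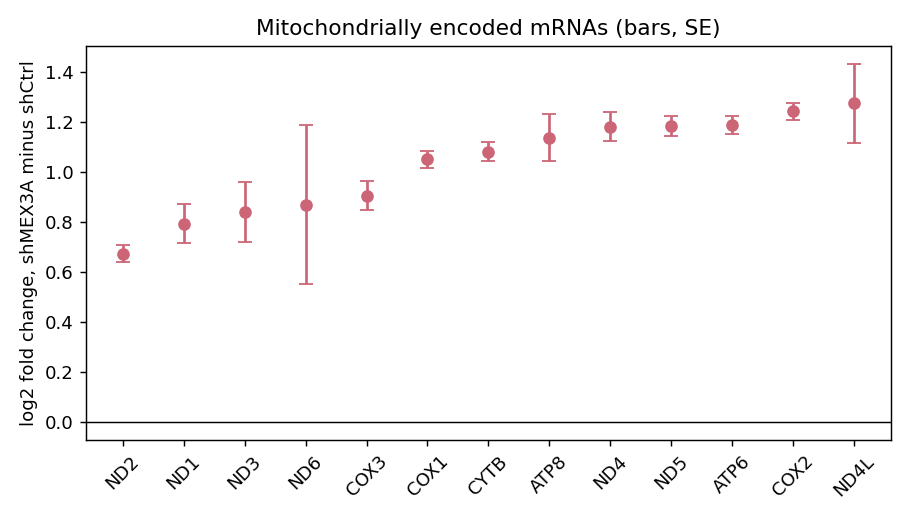
Log2 fold change, shMEX3A minus shCtrl (vertical axis), of the 13 mitochondrially encoded mRNAs (horizontal axis), with the standard error as bars. All 13 values lie above 0, and 12 of the 13 pass the test.

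Nuclear genes for mitochondrial proteins fell on balance in 4 lists, with small medians. Among the complex I subunits 22 of 37 fell and 2 rose, with a median of -0.20. NDUFB10 fell by 0.84 and NDUFS1 by 0.31 on the log2 scale, while NDUFV3 rose by 0.26 and NDUFV2 by 0.11. Among the subunits of complexes II to V 24 of 38 fell and 2 rose (median -0.16), with ATP5F1C, the gamma subunit of ATP synthase, at -1.65 (SE 0.035) and SDHD of complex II at -1.25 (SE 0.053). The 2 that rose were UQCRC1 (0.14) and ATP5MC3 (0.17). Among mitochondrial ribosomal proteins 53 of 76 fell and 6 rose (median -0.23), with MRPS7 at -0.97, MRPS27 at -0.45, MRPL4 at 0.37 and MRPS25 at 0.25. Among protein import genes 20 of 32 fell and 5 rose (median -0.21), with TOMM6 at -0.68, PMPCB at -0.56, TIMM17B at 0.71 and TOMM34 at 0.47. The adjusted p of camera was 0.00874 for complex I, 0.00859 for complexes II to V, 0.000216 for the ribosomal proteins and 0.0232 for import. With an estimated correlation the adjusted p values were 0.596, 0.560, 0.560 and 0.490. Once GC content and length were corrected for, a step chosen after seeing the data, none of the 4 passed camera (adjusted p = 0.257, 0.477, 0.063 and 0.348, in the same order). Without shCtrl replicate 1 the complex I list (adjusted p = 0.0536) and the import list (0.0581) lost their calls, and the import list also lost it with a filter of at least 1 CPM (0.0529) and on the genes with a GC value alone (0.0528). NDUFV2 lost its call without shCtrl replicate 2 (adjusted p = 0.0573) or shMEX3A replicate 2 (0.0648), and without genes that carry GCAAGA in the 3' UTR (0.07 in log2, adjusted p = 0.110), an alternative chosen after seeing the data. With GC and length offsets the log2 fold change was 0.41 for NDUFV2, 0.07 for UQCRC1, 0.27 for ATP5MC3 and -0.31 for PMPCB, all still called.

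Cell cycle genes fell. All 40 tested genes of the G2/M and mitosis list fell, with a median of -0.89. CENPF, a kinetochore protein, went from 168 ± 2.52 to 74.1 ± 0.922 CPM (log2 fold change -1.18, SE 0.033), and TOP2A, a DNA topoisomerase, from 191 ± 2.84 to 98.7 ± 2.13 CPM (-0.95, SE 0.032). In the G1/S and DNA replication list 33 of 38 fell and 1 rose (median -0.57). The transcription factor E2F2 changed by -1.71 (SE 0.065) and the ribonucleotide reductase subunit RRM2 by -0.87 (SE 0.038). The one that rose was CCNE1, cyclin E1, by 0.20 (SE 0.068). Its call was lost without shCtrl replicate 2 (adjusted p = 0.0728), shCtrl replicate 3 (0.0638), shMEX3A replicate 2 (0.0832) or shMEX3A replicate 3 (0.0653), and with the replicate number as a block (0.0529). The lists passed camera with adjusted p values of 1.89e-13 and 1.79e-08. With an estimated correlation these were an adjusted p of 0.102 and of 0.080.

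Genes under interferon and NF-kB control rose in most of their tested members. Of 31 interferon-stimulated genes 19 rose and 4 fell (median 0.45), with MX1 at 2.52 and the antiviral enzyme OAS3 at 1.04, against IFIT5 at -0.58 and IFIT2 at -0.49. Of 19 NF-kB and cytokine genes 14 rose and 4 fell (median 0.47). The cytokine IL6 rose from 25.5 ± 1.51 to 85.6 ± 0.807 CPM (log2 fold change 1.75, SE 0.043) and LIF by 1.65, while CXCL5 fell by 0.28 and the mitochondrial superoxide dismutase SOD2 by 0.14. The fall of CXCL5 lost its call with GC and length offsets (log2 fold change -0.02, adjusted p = 0.607). The adjusted p of camera was 0.00859 and 0.00442 for the lists in this order (adjusted p = 0.182 and 0.221 with an estimated correlation).

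The mesenchymal transition list moved up, with 15 of 21 genes higher and 4 lower (median 0.64). COL1A1 rose by 3.16 on the log2 scale. The 4 that went the other way were VIM and the transcription factors ZEB2, TWIST1 (-0.44) and ZEB1 (-0.34). VIM, the intermediate filament vimentin, fell from 3984 ± 107 to 1139 ± 3.25 CPM (log2 fold change -1.81, SE 0.031) and the repressor ZEB2 fell by 0.92. Of the 12 fibroblast markers fixed beforehand, only 5 passed the low-count filter and were tested. Among these 5, 4 rose and 0 fell (median 0.90). That list shares COL1A1 and COL1A2 with the mesenchymal one, and COL1A2 rose from 570 ± 7.11 to 1140 ± 12.8 CPM. Among immediate early genes 16 of 21 rose and 2 fell (median 0.60), with DUSP1 at 1.80 and FOSL1 at 1.61 against DUSP6 at -0.45 and EGR1 at -0.39. Of 11 replication-dependent histone genes 9 rose and 0 fell (median 0.84), led by H2AC6 (1.20) and H1-2 (1.00). Histone mRNAs lack a poly(A) tail in the main, and neither this nor reads shared between copies was examined here. The adjusted p of camera was 0.00442 for the mesenchymal list, 0.00859 for fibroblast markers, 0.00117 for immediate early genes and 0.00658 for histones. With an estimated correlation the adjusted p values were 0.213, 0.195, 0.182 and 0.195.

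NRF2 antioxidant genes and ribosomal protein genes fell on balance. Of 22 NRF2 genes 17 fell and 3 rose (median -0.28). NQO1, a quinone reductase, went from 1185 ± 45.3 to 603 ± 18.0 CPM (log2 fold change -0.97, SE 0.032) and the aldo-keto reductase AKR1C3 changed by -1.34, while ABCC2 rose by 0.43 and the malic enzyme ME1 by 0.29. Of 62 cytosolic ribosomal protein genes 37 fell and 3 rose (median -0.16). RPL3 went from 2513 ± 72.8 to 925 ± 21.0 CPM (-1.44, SE 0.031) beside the fall of RPS24, while RPL30 rose by 0.22 and RPL23 by 0.20. With GC and length offsets, chosen after seeing the data, 33 ribosomal protein genes fell and 12 rose (median -0.10, camera adjusted p = 0.0317), and ME1 was at 0.46, RPL30 at 0.40 and RPL23 at 0.36. The adjusted p of camera was 0.00511 and 0.000345 (adjusted p = 0.182 and 0.560 with an estimated correlation).

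**Figure D3:**
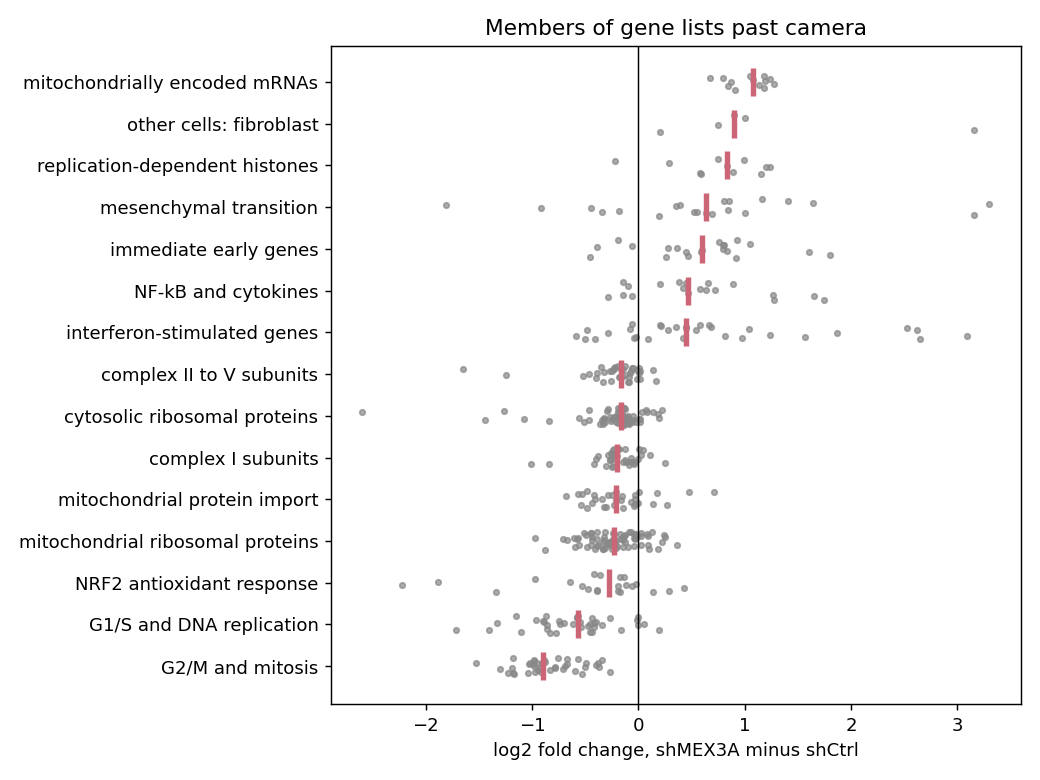
Log2 fold change, shMEX3A minus shCtrl (horizontal axis), of each tested member (points) of gene lists that passed camera (vertical axis), with the list median as a bar. The G2/M list lies wholly below 0 around its median of -0.89, and the mitochondrially encoded mRNAs lie above 0 around 1.08.

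In all, 16 of the 40 lists passed camera with its preset correlation, 8 up and 8 down, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.080 and 8 lists had an unadjusted p under 0.05. The estimate lay above the preset 0.01 for some of the 16, such as complex I (0.433) and cytosolic ribosomal proteins (0.447). It lay below 0.01 for G1/S (-0.02), interferon-stimulated genes (-0.0145), fibroblast markers (-0.047) and NRF2 genes (0.00313). A higher correlation therefore does not account for the lost calls of these last lists. The self-contained test fry called 36. Adjusted over the list alone, the counts in the 16 lists differed for mitochondrial ribosomal proteins (7 rose), cytosolic ribosomal proteins (36 fell) and immediate early genes (17 rose, 3 fell).

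The other 24 lists did not pass camera, although many of their members changed. For the metabolic lists, 5 rose and 13 fell of 25 TCA cycle genes, 6 and 13 of 23 in fatty acid oxidation, 10 and 9 of 22 in glycolysis, 7 and 7 of 15 in fatty acid synthesis, and 6 and 12 of 22 in cholesterol synthesis and uptake. For mitochondrial upkeep, 5 rose and 15 fell of 25 fusion, fission and cristae genes, 12 and 7 of 25 in mitophagy, 7 and 8 of 20 biogenesis regulators, and 3 and 5 of 14 chaperones and proteases. In the stress lists, 7 rose and 19 fell of 34 in the integrated stress response, 7 and 12 of 22 in the ER unfolded protein response, 4 and 8 of 16 in superoxide and peroxide detoxification, 5 and 7 of 19 in ferroptosis and iron, 10 and 9 of 21 in hypoxia, and 18 and 9 of 32 apoptosis regulators. In the growth and identity lists, 7 rose and 14 fell of 27 MYC targets, 8 and 2 of 16 epithelial genes, 8 and 7 of 19 matrix proteases and integrins, 6 and 8 of 14 clear cell carcinoma markers, and 5 and 7 of 14 Wnt and stem cell genes. The MEX3 family had 3 higher and 1 lower. Most markers of other cells did not pass the low-count filter. Those tested gave 4 rises of 4 for leukocytes (16 fixed beforehand), 2 rises and 1 fall of 5 for endothelium (12 fixed), and 2 falls of 3 for hepatocytes (12 fixed). Median, mean and test differed in sign for 5 lists, which were the MEX3 family, glycolysis, hypoxia, fatty acid synthesis and clear cell carcinoma markers. Leaving out 1 library brought a call for 3 lists. The fusion list passed without shCtrl replicate 2 (adjusted p = 0.0304), shCtrl replicate 3 (0.0495) or shMEX3A replicate 3 (0.0480). The integrated stress list (0.0448 and 0.0495) and the leukocyte list (0.0304 and 0.0495) passed without shCtrl replicate 2 or shCtrl replicate 3. Without the low-count filter the fusion (adjusted p = 0.00784), TCA cycle (0.0476), integrated stress (0.00886), leukocyte (0.0177) and hepatocyte (0.0359) lists passed. Under alternatives chosen after seeing the data, the integrated stress list passed with GC and length offsets (0.0341), and apoptosis regulators (0.0468) and MYC targets (0.0412) passed without carriers of GCAAGA.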

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

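All alternatives kept the direction of MEX3A (log2 fold change -1.68 to -1.86) and of each gene under the naming rule. All but 2 of the counts stayed within 1.5-fold. A filter of at least 1 CPM left 720 genes higher at least 2-fold, since it tests fewer weakly expressed genes. Leaving out carriers of GCAAGA, chosen after seeing the data, took genes lower at least 2-fold from 871 to 576. It removed fewer of the genes higher at least 2-fold, which went from 1090 to 861. Among the genes scanned, GCAAGA lay in 46.4% of those lower at least 2-fold and in 30.0% of the others. The motif was picked from these fold changes, so this is not a separate test. With an estimated correlation 0 lists passed, and fry called 36. With 1 library left out MEX3A ranged from -1.68 to -1.77 and the lists passing camera from 14 to 19. Of the values for named genes under alternatives, 1239 kept their side of the threshold and 11 lost it, and of those for single lists 637 kept it, 24 lost it and 15 gained it. Replicate numbers did not pair the arms: deviations of libraries with the same number correlated between -0.077 and 0.077, and 2 of 6 libraries correlated best with their own number. With the replicate block 5247 genes were higher and 5504 lower, and 10699 calls were shared with the unblocked fit. Among named genes CCNE1 alone lost its call under the block (adjusted p = 0.0529). GC and length offsets, chosen after seeing the data, called 10410 genes, of which 8976 shared their call and direction with the main test (9991 on the same genes without offsets). The share of calls that were higher went from 48.8% to 51.4% (49.7% on the same genes without offsets), so more genes were then higher than lower. At least 2-fold changes turned to 741 higher and 747 lower (824 and 752 on the same genes without offsets).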

Other observations

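The lists of TGF-beta response and methionine cycle genes, the GC and length test of the nuclear lists, the comparison of mitochondrial mRNAs with rRNAs, and the 7-mer test by base composition were chosen after the result was seen. Among 27 TGF-beta response genes, counted without the leading genes that prompted the list, 21 rose and 4 fell, with a median log2 fold change of 0.58 (camera adjusted p = 0.00018, but adjusted p = 0.0827 with an estimated correlation). COL7A1 rose by 1.81 (SE 0.047), SKI by 0.95 (SE 0.031) and SMAD7 by 0.62 (SE 0.053), while ID1, which BMP signals induce, fell by 1.21 (SE 0.033). The others that fell were TGFB2 at -1.60 (SE 0.459), VASN at -0.76 (SE 0.175) and TGIF1 at -0.39 (SE 0.030). A TGF-beta transcription response is a hypothesis that this list, drawn up after its leading genes had been seen, cannot settle. The methionine cycle genes other than MAT2A had an adjusted p of 0.456 in camera and moved both ways, with the transporter SLC43A2 at 1.69, SRM at 0.63 and MTRR at -0.39, which decides nothing about a change across the cycle.

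Genes with TGCAAGA in the 3' UTR were lower in shMEX3A, the strongest shift of the 7-mers scanned (1386 genes, -0.28 in log2 after adjusting for GC content and length, z = -15.9, permutation p = 0.001, the smallest the permutations can give). The other 418 rearrangements of its bases without GCAAGA had a median shift of -0.0147 (bound -0.14) and a lowest shift of -0.12. All these shifts were already adjusted for GC content, so they cannot test it. They argue against base composition beyond GC content, although TGCAAGA was picked for its shift, which favours such a gap. The 83 carriers without a MEX-3 recognition element lay below the 3025 non-carriers without one (-0.39, bound 0.154). For these 83 genes this argues against loss of MEX3A from that motif. They are among the carriers whose fold changes picked the 7-mer, however, which favours a fall in them. Most 3' UTRs hold the motif, so the other carriers were not covered. The 8442 genes with the motif but no TGCAAGA shifted by 0.03 (SE 0.014) against genes with neither. The shift was deeper for sites in the 3' UTR than elsewhere (difference -0.20, bound 0.047), as seed pairing of the shMEX3A guide would give, although the 7-mer was picked by its shift in the 3' UTR, which favours that side. The 7-mer occurs once in the coding sequence of MEX3A, at base 457 of 6124 of the transcript (chromosome 1, 156077674 to 156077680, exon 2), although 27.5% of the 7-mers scanned occur somewhere in that transcript, so an effect of the hairpin on other transcripts stays a candidate explanation for part of the falls, with the guide sequence not used here. GCAAGA lay in the 3' UTR of CPE, SLC4A4, ADAMTS3 and PDCL3 among the 10 largest falls and of TFPI2, PDE2A, ADAM19 and INHBA among the 10 largest rises, with TGCAAGA there in CPE and ADAMTS3 alone. Over the genes scanned, GCAAGA lay in 46.4% of those lower at least 2-fold and 30.0% of the others, and TGCAAGA in 24.7% and 9.96%. Against genes without GCAAGA, the adjusted mean was -0.08 for GCAAGA alone, -0.17 for GCAAGAA, -0.27 for TGCAAGA and -0.37 for TGCAAGAA. These values use the fold changes that picked the 7-mer, so they are not a separate test.

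Mitochondrially encoded mRNAs rose while the 4 nuclear mitochondrial lists fell. The mRNAs rose further than the 2 mitochondrial rRNAs, by 0.77 in log2 (bound 0.312, 2 standard errors over genes). This cannot decide whether mitochondrial RNA rose in general, since mRNA libraries were prepared and rRNA reads in them need not track rRNA levels. GC content and length do not account for the rise of the mRNAs, since the corrected median was 1.26. For the nuclear lists, all 4 of 4 kept their call without carriers of GCAAGA, but of the 3 that pass on the genes with a GC value alone, where import did not pass (adjusted p = 0.0528), 0 kept it with GC and length offsets. On those genes the medians moved from -0.18 to -0.08 (complex I), -0.13 to -0.05 (complexes II to V), -0.21 to -0.10 (ribosomal proteins) and -0.19 to -0.14 (import), within quartiles as wide as -0.33 to 0.09 for the ribosomal proteins. GC content and length may therefore account for part of the nuclear fall, and an effect of MEX3A on these genes stays open.

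Most tested genes changed, and the number called stayed high after GC and length correction (10410, against 10296 uncorrected on the same genes), which argues against these as the whole cause. Loss of MEX3A and effects of the hairpin on other transcripts stay open, since each arm had 1 hairpin. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In edgeR the real split gave 5336 genes higher, 5589 lower, 1090 higher and 871 lower at least 2-fold, and the highest of the other 9 splits gave 0 for each (44 to 114 genes at an unadjusted p under 0.05). Only 1 of the 10 splits, the real one, gave as many. Each other split mixes the arms, so the difference between the arms enters the spread within its groups. The 0 calls there could thus be foreseen and lend the real split no support. For the gene lists the real split moved 16 and others up to 12, and each other split still sets 2 libraries of an arm against 1, so that part of the difference between the arms stays in it. The lists for mitochondrially encoded mRNAs, G1/S and G2/M passed in 9 of the 9 other splits, which a shift left in those splits would also give. Genes with GTCGCCC in the 3' UTR rose by 0.14 (591 genes, z = 5.28, permutation p = 0.001, the smallest the permutations can give).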
